A study of Mus musculus with 8 samples.

How the data were processed

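Liver RNA of 8 samples was sequenced, 4 with floxed Ctcf and no Cre (WT) and 4 with floxed Ctcf and albumin-Cre (cKO). Per the labels' protocols, livers were frozen, RNA was taken with Trizol and libraries were made with an Illumina TruSeq RNA kit from total RNA. Reads were aligned with STAR 2.5.1 and quantified with RSEM against the mm10 genome, per the submitters' processing notes; the version of RSEM, the annotation and the strand setting are not given in the sources used here. The deposited files hold, per gene and library, RSEM expected counts, that is estimated counts that need not be whole because reads that fit several genes are divided between them, with effective lengths per the file headers. They also hold TPM, made by the authors from the same estimates by dividing by length and scaling to the same total in each library, and FPKM, which the authors deposited and which was not used here. Division of shared reads makes the values of paralogs such as the Mup genes, of overlapping genes and of antisense genes uncertain. The labels name separate samples with replicate numbers and do not say that each came from a separate mouse, so that p values measure the spread between these samples.

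The files list 52636 genes, of which 26668 had a count. Expected counts were rounded to whole numbers. Genes were kept with edgeR's filterByExpr by genotype (minimum count 10, minimum total 15), which left 15562. Libraries were scaled with TMM factors, which averaged 0.964 in WT and 1.038 in cKO, and genotypes were compared with edgeR 4.0.16 (R 4.3.3), using estimateDisp, a robust glmQLFit and glmQLFTest with Benjamini-Hochberg adjustment at 0.05. CPM and log2 changes were computed from those deposited counts, with CPM scaled to totals times TMM factors except for the level of Xist, the limit for a count of 0 and the filter of 1 CPM, which use totals alone. Standard errors of log2 changes were derived from the F statistic. Gene lists were tested with limma 3.58.1's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry, whose p tests whether the genes of a list move on balance in 1 direction. Single quantities were compared with exact two-sided permutation tests over 70 assignments. Similarity was measured on log2 CPM with a prior count of 2. No pair of libraries of the same genotype agreed within sampling noise (chi-square per degree of freedom of 26.1 or more), so each was counted once.

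On simulated counts for 15360 genes, 200 genes with a mean above 1 CPM were changed by a known amount and the rest were not. The cKO against WT test recovered 61.2% of 67 genes changed 1.5-fold, 92.5% of 67 changed 2-fold and 97% of 66 changed 4-fold. Of its calls 6.18% were unchanged genes. Far more genes were called in the real data, some of them at lower levels, so these rates need not hold there. A planted list was called and 0 of 36 random lists were. That simulation drew genes independently, whereas genes of a list vary together in real libraries, so it does not show how often camera calls lists by chance here.

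The comparison, the 37 lists and the naming rule were fixed before the data were examined. Sets of mesothelial, stellate-restricted, portal fibroblast and growth hormone pathway genes, gene families and splits for single lists were added afterwards. The rule named Ctcf and Ctcfl; the 12 largest rises and falls among genes with adjusted p under 0.05, a mean of at least 5 CPM and genotypes that did not overlap, without predicted symbols; examples from the 4 members of a list with the smallest p, with the opposite member of smallest p if it passed; and Pparg, Cd36, Cyp7a1, Srebf1, Ppara, Alb, Afp, Fgf21, H19, Igf2, Xist and Ddx3y. Further falls outside the Mup family, the next in size, and Igf1, Socs2, Cish, Gldn, Evpl, Spire2, Eif5a2, Parm1, Gm21887, AL591207.3 and Fam19a5, were named after their values were seen. Gene positions came from RefSeq's annotation of GRCm38, the assembly called mm10, matched by symbol or unique synonym for 14561 tested genes (93.6%). The reference genome sequence at hand was of another build and was not used.

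Alternatives fixed beforehand were DESeq2-type and upper quartile factors, library size alone, library size without the 20 most abundant genes, no filter, a filter of 1 CPM in 4 libraries, quasi-likelihood without robust and in its legacy form, an offset for effective length, the replicate number as a block, DESeq2 1.42.0, limma-voom, limma on log2(TPM + 1) and log2(TPM + 0.1), adjusted p under 0.01, a null of 1.5-fold, and leaving out each library. Thinning all libraries to the smallest total and removing the Mup genes were added after the data were seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.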

Results

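The transcriptome of whole liver was measured by RNA sequencing in 8 samples from C57BL/6 mice at 8 weeks of age. In 4 samples both Ctcf alleles carried loxP sites and no Cre recombinase was present (WT). In the other 4 the same alleles were combined with Cre driven by the albumin promoter, which is active in hepatocytes (cKO). CTCF is a zinc finger protein that binds DNA and takes part in the folding of chromatin into loops and domains. The comparison asked which transcripts differed in abundance in liver when Ctcf was deleted in albumin-expressing cells. None of the 8 samples carried Cre without floxed Ctcf, so an effect of Cre itself cannot be told apart from loss of Ctcf. Totals of assigned counts ran from 43.9 M to 57.3 M per library, with 46.1 ± 2.94 M in WT and 52.4 ± 3.28 M in cKO (mean ± SD, n = 4 each; exact two-sided permutation test, p = 0.0571, smallest possible p 0.0286). A count of 0 in a library allowed a level of up to 0.0524 to 0.0683 CPM (read counts scaled to library size), a limit that covers counting error only. That limit and the level of Xist are scaled to the total alone, and other CPM values to totals adjusted with TMM factors.

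In CPM the targeted gene was lower in every cKO library than in every WT library. Ctcf (ENSMUSG00000005698, mm10 chromosome 8, 105636474 to 105682922) stood at 16.5 ± 0.41 CPM in WT and 12.2 ± 0.95 CPM in cKO (mean ± SD, n = 4 each; exact two-sided permutation test, p = 0.0286, the smallest this design allows). Its log2 change was -0.44 (SE 0.08, edgeR adjusted p = 0.00202), so that 73.8% of the WT level remained. The counts were summed over the whole gene, and the labels do not say which exons were deleted. They also include cells of whole liver that do not express albumin, so 73.8% is not the level left in the deleted cells. In TPM (transcript abundance scaled for length and depth) the means were 5.73 ± 0.33 and 5.06 ± 0.36. There the genotypes overlapped, with 5.42 in cKO replicate 3 and 5.34 in WT replicate 4. Limma on log2(TPM + 1), without TMM factors, gave a log2 change of -0.15 with an adjusted p of 0.119. Over all 24 alternatives the log2 changes were -0.46 to -0.15. Ctcfl, the paralog normally used in the male germline, had 1.87 ± 0.20 CPM in WT and 1.43 ± 0.22 CPM in cKO and did not pass (log2 change -0.38, edgeR adjusted p = 0.0925).

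**Figure D1:**
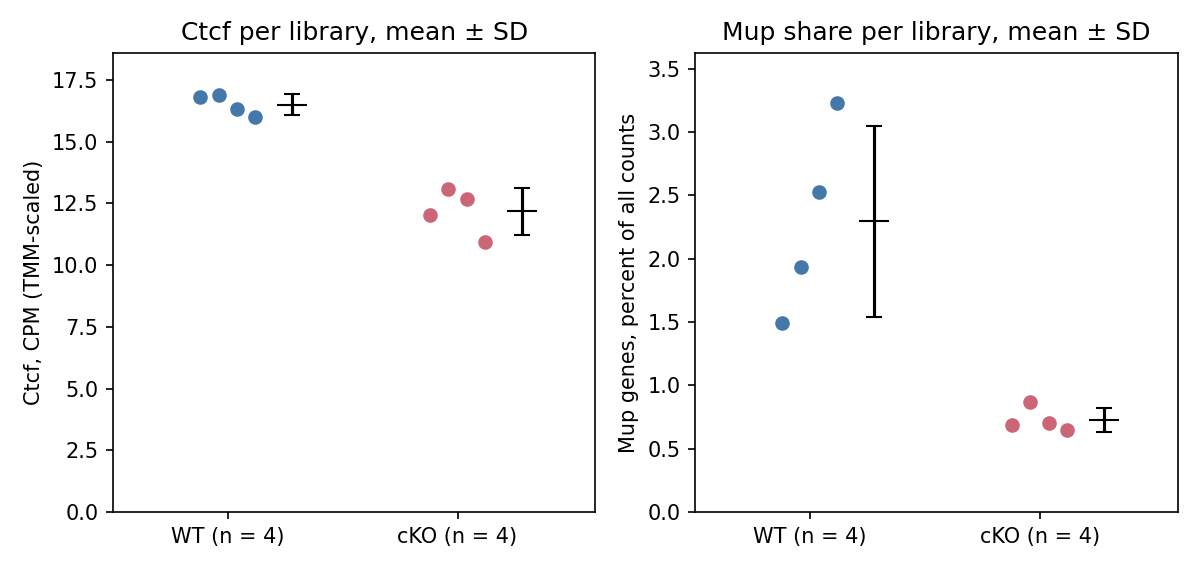
Ctcf in CPM (left) and the percentage of all counts taken by the major urinary protein (Mup) genes (right), with 1 point per library and the mean ± SD of 4 libraries beside the points. Ctcf averaged 16.5 CPM in WT and 12.2 CPM in cKO, and the Mup share averaged 2.30% and 0.725%.

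Genotype was the main axis of variation between libraries. The first principal component of log2 CPM held 48.9% of the variance and placed the WT libraries at negative and the cKO libraries at positive values. The second held 13.5% and mainly spread the WT libraries, from -39.6 for WT replicate 4 to 26.7 for WT replicate 1. Pearson correlations were 0.983 to 0.990 within genotypes and 0.966 to 0.978 between them, across genes, which are not independent replicates.

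**Figure D2:**
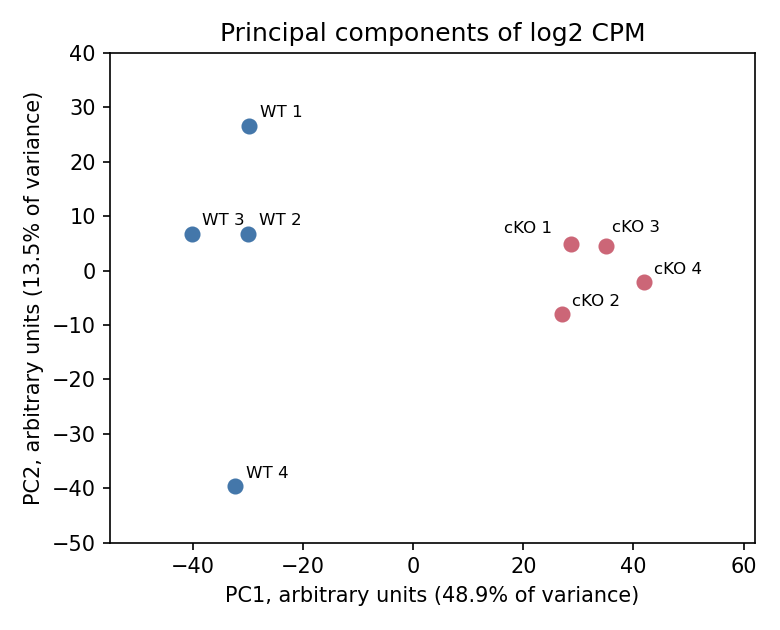
Scores of the 8 libraries on the first (x axis) and second (y axis) principal component of log2 CPM over the tested genes, with 1 point per library. WT replicate 4 lies at -39.6 on the second component, apart from the other 7 libraries.

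Of 15562 genes tested, 2386 were higher and 2352 lower in cKO at an edgeR adjusted p under 0.05, which together is 30.4% of the genes. At least a 2-fold change was estimated for 580 of the higher and 277 of the lower genes. Every cKO library lay beyond every WT library for 2035 of the higher and 2013 of the lower genes, and for 30.6% of all tested genes, where chance gives 2.86%. The balance between the directions depended on the scaling: library size alone gave 3624 higher and 1335 lower, and library size without the 20 most abundant genes 3223 and 1442. Limma on log2(TPM + 1), which used no TMM factors and also differs in the test, the unit and the 11651 genes tested, gave 3189 and 762. Against a 1.5-fold change as the null, 326 were higher and 121 lower.

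The largest rises and falls were taken among genes with a mean of at least 5 CPM and no overlap of the genotypes, without predicted symbols. Cyp2a4, a cytochrome P450 that is higher in female than in male mouse liver, rose from 1.78 ± 0.76 to 27.7 ± 3.82 CPM (log2 change 3.94), and Cyp2b10, a target of the receptor CAR, from 3.69 ± 1.67 to 28.5 ± 12.3 CPM. Cd36, a fatty acid transporter, rose from 10.1 ± 2.04 to 50.9 ± 3.84 CPM (log2 change 2.34, SE 0.14, edgeR adjusted p = 4.43e-06), and Apoa4, an apolipoprotein, from 775 ± 234 to 4293 ± 922 CPM. The stress-induced transcriptional regulator Nupr1 rose from 1.43 ± 0.08 to 14.4 ± 0.83 CPM. The cell cycle regulator Ccnd1 and the Myc family member Mycl rose by log2 2.63 and 2.77. The remaining genes of the 12 with the largest rises were Ly6d, Cd63, Ifi27l2b, Ugt1a5 and the imprinted noncoding RNA Rian, with log2 changes of 3.35, 2.85, 2.80, 2.54 and 2.05 (values are mean ± SD of 4 libraries per genotype).

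Of the 12 largest falls at that level 10 were in the Mup genes, a cluster of near-identical genes for secreted pheromone carriers that are abundant in male liver. They took 2.30 ± 0.75% of all counts in WT and 0.725 ± 0.098% in cKO (n = 4 each; exact two-sided permutation test, p = 0.0286). Of 19 Mup genes tested 18 were lower, and the log2 ratio of the family sums was -1.77. Because reads can be divided between the copies in different ways, the values of single Mup genes are uncertain: Mup15, Mup17, Mup2, Mup1, Mup7, Mup19, Mup12, Mup16, Mup14 and Mup8 had log2 changes of -6.85, -6.74, -5.00, -4.41, -4.34, -4.17, -3.67, -3.24, -2.93 and -2.79. WT replicate 4 had the highest Mup share (3.23%), and without it Mup15, Mup17, Mup2, Mup19, Mup16 and Mup8 had log2 changes of -4.82, -4.92, -3.09, -3.63, -2.52 and -1.53. Without cKO replicate 2 Mup7 had -5.19. The replicate block ended the calls of Mup15, Mup17, Mup2, Mup16 and Mup8. Of 23 alternatives 8 ended the call of Mup2, among them no filter and limma-voom, and 10 that of Mup8, among them no filter, library size alone, an offset for effective length and thinning. Leaving out WT replicate 3 or any 1 of the 4 cKO libraries ended those of Mup2 (adjusted p 0.0561 to 0.0952) and Mup8 (0.0665 to 0.114), and leaving out cKO replicate 4 that of Mup15 (0.053). The other genes among the 12 largest falls were Hsd3b5, a steroid dehydrogenase higher in male liver (14.9 ± 4.11 to 0.310 ± 0.271 CPM, log2 change -5.58, and -6.28 without cKO replicate 2), and Hamp2, a paralog of the hepcidin gene (log2 change -2.85).

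Since Mup genes filled 10 of those 12 places, falls outside the family that came next were also taken, a choice made after their values were seen. Wfdc2, Col27a1, Tk1, Syt3, Tbx3os1 and Elovl3 had log2 changes of -1.84, -1.82, -1.60, -1.55, -1.54 and -2.10, and the replicate block ended the call of Elovl3. Asns, which makes asparagine, and Derl3, of protein degradation from the endoplasmic reticulum, had log2 changes of -2.17 and -2.02. Without WT replicate 4 they had -1.64 and -1.37. Cyp7b1, Fgl1 and Angptl8 had -1.69, -1.64 and -1.57, with edgeR adjusted p values of 0.0333, 0.0243 and 0.0491. The calls of Asns, Derl3, Cyp7b1, Fgl1 and Angptl8 were ended by 2, 7, 6, 6 and 13 of 24 alternatives. The libraries that ended a call when left out were cKO replicates 3 and 4 for Asns (adjusted p 0.0516 to 0.0531), WT replicate 3 and each cKO replicate for Derl3 (0.067 to 0.0953), and WT replicate 3 and cKO replicates 1, 3 and 4 for Cyp7b1 (0.0762 to 0.0909). They were WT replicate 4 and each cKO replicate for Fgl1 (0.0535 to 0.0717) and all but cKO replicate 1 for Angptl8 (0.0589 to 0.107).

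**Figure D3:**
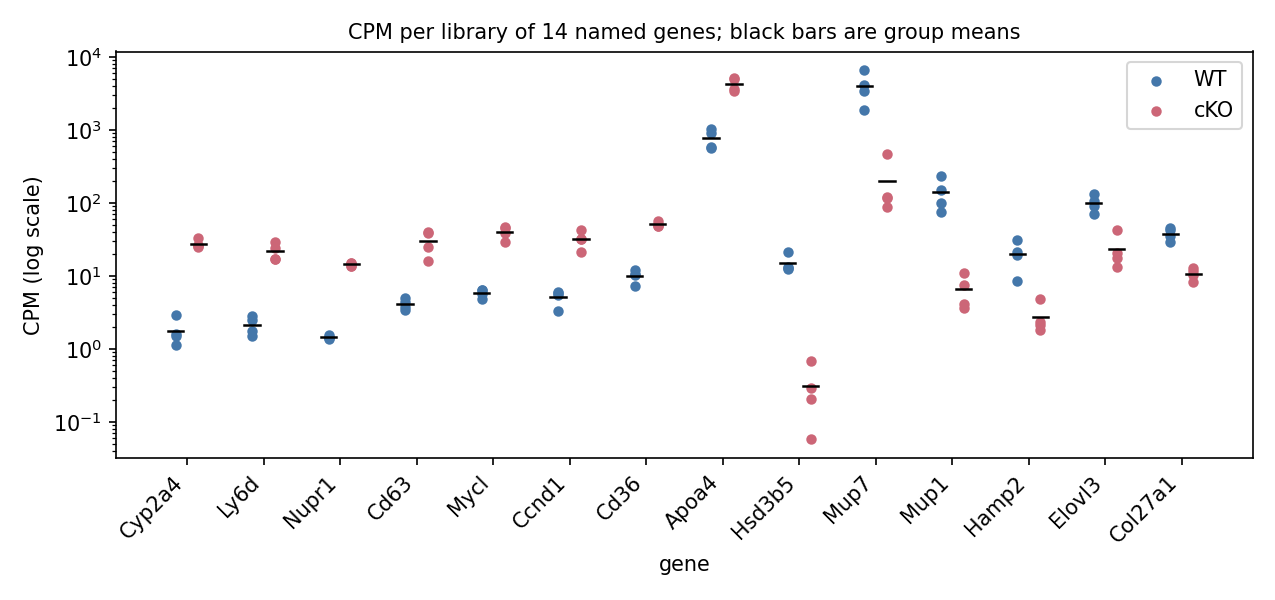
CPM on a log axis (y) of 14 named genes (x), with 1 point per library and a bar at the mean of 4 libraries. Hsd3b5 averaged 14.9 CPM in WT and 0.310 CPM in cKO, and Cd36 10.1 and 50.9 CPM.

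Gene groups were described with 37 lists fixed before the data were examined. With camera's preset correlation, 14 passed an adjusted p of 0.05, with 11 shifted up and 3 down, and 0 of the 37 passed with an estimated correlation. Of the 14, 6 were then under an unadjusted p of 0.05. The number of lists was also reached by other splits of the libraries. Of the other 34 ways to split the 8 libraries 4 against 4, 15 gave at least 14 lists and the highest gave 21. These are not a pure measure of chance, since some keep most libraries of a genotype together and so part of its contrast. Splits with equal numbers of each genotype on either side gave 6 to 17 lists. None of the 34 gave more than 6 genes in a direction, but each mixes the genotypes, which widens the spread within groups. For 3 lists, those of stellate cells and fibroblasts, of female-biased genes and of fetal liver and liver tumour genes, no other split gave a camera p as small. The counts of members below rest on the test of each gene, and are given over all tested genes and adjusted over the list alone.

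Lipid genes moved in both directions. Of 29 tested genes of lipid uptake and lipid droplets, 9 were higher and 2 lower (10 and 3 adjusted over the list alone; median log2 change 0.18), with Cd36, the droplet coat gene Plin2 (log2 change 0.77) and Cidec, which promotes droplet fusion (8.82 ± 2.83 to 36.3 ± 11.9 CPM), higher and Fitm1 lower (-0.83). The list had a camera adjusted p of 0.00508 and an adjusted p of 0.316 with an estimated correlation. Of 25 genes of fatty acid synthesis 9 were higher and 4 lower (9 and 4 adjusted over the list alone; median 0.35): Elovl5, Scd2, Elovl6 and Acaca had log2 changes of 0.81, 0.76, 0.98 and 0.58, and Fasn, the fatty acid synthase, -0.49. That list's adjusted p was 0.0405, and 0.344 with an estimated correlation. Its call was lost with library size scaling (0.0533) and without WT replicate 4 (0.0643) or cKO replicate 4 (0.0847). Of 33 genes of fatty acid oxidation and ketogenesis, 10 were higher and 1 lower (12 and 2 adjusted over the list alone; median 0.22; camera adjusted p = 0.0044, adjusted p = 0.641 with an estimated correlation). Ehhadh, of peroxisomal oxidation, had a log2 change of 1.15, and Cyp4a10, Hadhb and Cyp4a14 had 0.59, 0.47 and 0.63. The lower member, Vnn1, had a log2 change of -0.37 (edgeR adjusted p = 0.0359), a call that 12 of 24 alternatives ended, among them leaving out WT replicate 1, 2 or 4 or cKO replicate 1, 2 or 4 (0.0775 to 0.103).

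Genes of cholesterol synthesis were mostly lower. Of 25 tested, 17 were lower and 1 higher, also adjusted over the list alone, with a median log2 change of -0.47 (camera adjusted p = 2.19e-06, adjusted p = 0.328 with an estimated correlation). Fdps and Idi1, of isoprenoid synthesis, fell from 37.3 ± 8.02 to 17.3 ± 1.98 and from 16.7 ± 3.85 to 7.75 ± 1.63 CPM, and Lss and Ebp had log2 changes of -0.58 and -0.46. An offset for effective length and limma on log2 TPM ended the call of Lss. Dhcr7, the higher member, had a log2 change of 0.27 (edgeR adjusted p = 0.0459), a call that 7 of 24 alternatives ended, among them leaving out WT replicate 1, 2 or 3 or cKO replicate 2 or 4 (0.0642 to 0.131). Srebf1, a regulator of fatty acid synthesis, was lower (log2 change -0.89). Pparg did not pass (4.76 ± 0.84 and 3.53 ± 0.58 CPM, log2 change -0.43, edgeR adjusted p = 0.0555). It was past the threshold under 4 of 24 alternatives: 0.0349 with an offset for effective length, 0.0345 with the replicate block, 0.0214 without WT replicate 4 and 0.0341 without cKO replicate 1. Ppara (log2 change 0.21, edgeR adjusted p = 0.139), the hormone gene Fgf21 (0.83, 0.161) and Cyp7a1, the rate-limiting enzyme of bile acid synthesis (-0.03, 0.948), did not pass either. Ppara was past the threshold under 5 of 24 alternatives, and its log2 change ran from 0.13 to 1.00 over them all.

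Genes with a known difference between male and female liver were shifted in opposite directions. Of 23 male-biased genes 15 were lower and 0 higher (17 and 0 adjusted over the list alone; 0 higher also at an unadjusted p under 0.05, with DESeq2 and with limma-voom), with a median log2 change of -1.10 (camera adjusted p = 3.62e-11, adjusted p = 0.287 with an estimated correlation). Besides Hsd3b5, Mup3, Cspg5 and the anion transporter Slco1a1 had log2 changes of -1.42, -1.73 and -1.10. Other splits of the libraries gave this list as small a camera p in 4 of 34 cases. Of 19 female-biased genes 7 were higher and 1 lower, also adjusted over the list alone, with a median of 0.52 (camera adjusted p = 0.000278, adjusted p = 0.0628 with an estimated correlation). Cyp2a4 was 1 of them, Rtn4 had a log2 change of 1.17, Hao2 rose from 0.029 ± 0.035 to 0.554 ± 0.139 CPM (log2 change 4.18, and 4.99 without WT replicate 3), and Cyp2g1 was the lower member (-1.20). The labels do not give the sex of the mice. Xist, transcribed in females, had at most 0.263 CPM in any library, and Ddx3y, on the Y chromosome, 12.9 ± 1.62 CPM in WT and 15.4 ± 1.62 CPM in cKO (edgeR adjusted p = 0.0895, 0.0285 without WT replicate 4, and past the threshold under 6 of 24 alternatives).

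Hepatocyte genes were lower in part, and genes of fetal liver and liver tumours higher in part. Of 32 hepatocyte identity genes 14 were lower and 1 higher (15 and 1 adjusted over the list alone; median -0.22; camera adjusted p = 0.00312, adjusted p = 0.239 with an estimated correlation). The secreted proteins Fetub, Serpina1c, Ttr and Vtn had log2 changes of -0.58, -0.62, -0.68 and -0.44, while the urea cycle gene Cps1 had 0.58, a call lost without WT replicate 3 (0.53, adjusted p = 0.0517). Alb did not pass (log2 change 0.14, edgeR adjusted p = 0.514). Of 24 genes of fetal liver and liver tumours 11 were higher and 1 lower (12 and 1 adjusted over the list alone; median 0.60; camera adjusted p = 5.21e-05, adjusted p = 0.0628 with an estimated correlation), among them Cd24a (log2 change 1.63), Ly6d, the transporter Abcc4 (1.28 ± 0.24 to 3.14 ± 0.27 CPM) and Golm1 (1.33), with Rec8 lower (-0.75). Of the 24, 8 are also in other lists. Afp, the fetal serum protein, stood at 0.903 ± 0.067 CPM in WT and 1.12 ± 0.20 CPM in cKO and did not pass (edgeR adjusted p = 0.229). Of 27 p53 response genes 8 were higher and 0 lower (9 and 0 adjusted over the list alone and 9 and 0 at an unadjusted p under 0.05, with DESeq2 and with limma-voom; median 0.16; camera adjusted p = 0.0229, adjusted p = 0.596 with an estimated correlation, and 0.0816 without cKO replicate 2). Tnfrsf10b, Phlda3, Ccng1 and Eda2r had log2 changes of 1.42, 1.27, 0.39 and 1.49. Tnfrsf10b and Eda2r were too low for the filter of 1 CPM in 4 libraries.

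Markers of cells other than hepatocytes moved apart from each other. Of 28 stellate cell and fibroblast markers 25 were higher and 0 lower, also adjusted over the list alone, at an unadjusted p under 0.05, with DESeq2 and with limma-voom, with a median log2 change of 0.96 (camera adjusted p = 1.14e-26, adjusted p = 0.0628 with an estimated correlation). Lrat, of vitamin A storage, rose from 4.66 ± 0.20 to 12.8 ± 0.82 CPM, the matrix proteoglycan Dcn from 65.3 ± 3.71 to 194 ± 27.1 CPM, and Pdgfra and Lum had log2 changes of 1.63 and 1.89. Of 15 markers of lipid-associated and recruited macrophages 11 were higher and 1 lower, also adjusted over the list alone (median 0.86; camera adjusted p = 4.65e-05, adjusted p = 0.156 with an estimated correlation), with Gpnmb, Cd63 and Mmp12 at log2 changes of 1.90, 2.85 and 3.24 and Spp1 lower at -0.68. Without WT replicate 2 Mmp12 had 4.47. Gpnmb and Mmp12 were too low for the filter of 1 CPM in 4 libraries. Of 19 Kupffer cell and macrophage markers only Marco was higher (log2 change 0.61, 0 adjusted over the list alone; call lost without WT replicate 3, 0.54, adjusted p = 0.0504), with a list median of -0.08 and a camera adjusted p of 0.814.

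Of 20 T and NK cell markers 9 were higher and 0 lower, also adjusted over the list alone, with DESeq2 and with limma-voom (13 and 0 at an unadjusted p under 0.05; median 0.81; camera adjusted p = 0.000387, adjusted p = 0.286 with an estimated correlation). Cd8a, Ccl5, Cd3d and Nkg7 had log2 changes of 2.65, 2.05, 1.00 and 1.12. Cd8a, Cd3d and Nkg7 were too low for the filter of 1 CPM in 4 libraries, and Cd3d stood at 0.187 to 0.321 CPM in WT. An offset for effective length ended the call of Cd3d. Of 16 cholangiocyte markers 8 were higher and 1, Spp1, lower, also adjusted over the list alone (median 0.58; camera adjusted p = 7.1e-05, adjusted p = 0.229 with an estimated correlation). Cd24a, Cldn4 and Cldn7 had log2 changes of 1.63, 2.90 and 1.86, and Epcam rose from 1.10 ± 0.36 to 3.13 ± 0.33 CPM. Of the 16, 4 are also in other lists. Of 20 endothelial markers 4 were higher and 0 lower (1 and 0 adjusted over the list alone, 6 and 0 at an unadjusted p under 0.05, with DESeq2 and with limma-voom; median 0.32; camera adjusted p = 0.0223, adjusted p = 0.732 with an estimated correlation). Rspo3 had a log2 change of 1.19, while the calls of Mrc1, Wnt2 and Tek (0.46, 0.73 and 0.52) were ended by 6, 8 and 9 of 24 alternatives, with adjusted p values of 0.0594 to 0.0848, 0.053 to 0.124 and 0.0548 to 0.133 when a library was left out. Those libraries were WT replicates 1, 3 and 4 for Mrc1, WT replicates 2, 3 and 4 for Wnt2 (each with cKO replicates 1, 2 and 4), and WT replicates 3 and 4 and each cKO replicate for Tek. The endothelial list was lost with library size scaling (0.0533) and without WT replicate 4 (0.167), cKO replicate 1 (0.0504) or cKO replicate 4 (0.0792). With edgeR 0 members passed among 17 B and plasma cell, 6 neutrophil and 5 red blood cell markers, nor adjusted over the list alone (medians -0.22, 0.31 and 0.58; camera adjusted p = 0.554, 0.876 and 0.678). At an unadjusted p under 0.05 there were 1, 0 and 0, with DESeq2 0, 1 and 0, and with limma-voom 0 in each. The red blood cell list alone had a camera adjusted p of 0.00232 without WT replicate 2. Of 5 adipocyte markers Cidec was higher (median -0.07, mean 0.30, camera direction up, adjusted p = 0.466), and of 3 genes of neighbouring pancreas and gall bladder Cela1 and Cela2a were lower (log2 change -0.56 and -1.54; median -0.56; camera adjusted p = 0.12), both adjusted over the list alone as well. Of 21 alternatives, 4 ended the call of Cela2a, 2 of them leaving out WT replicate 4 (-1.29) or cKO replicate 4 (-1.22), with adjusted p values of 0.0514 and 0.0587.

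**Figure D4:**
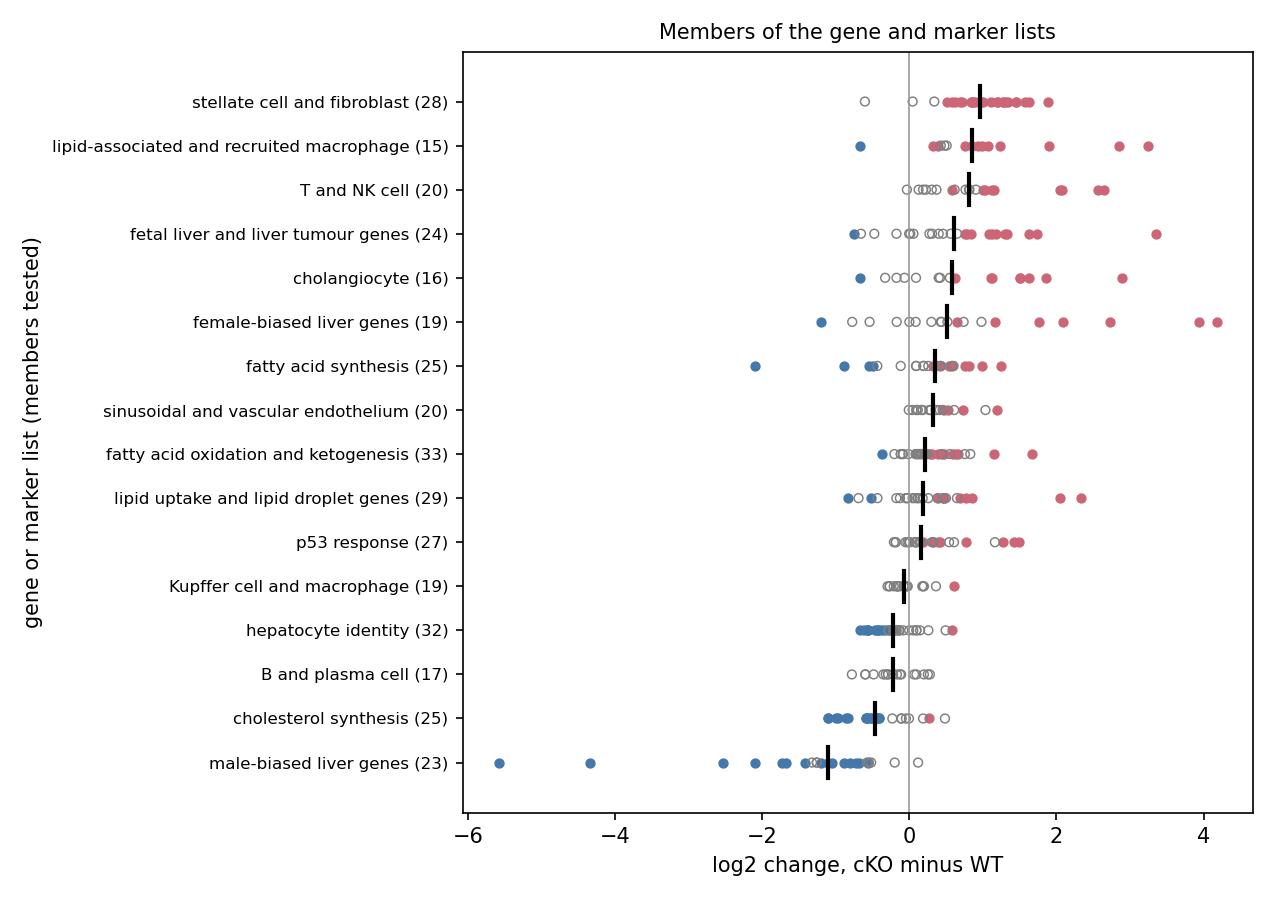
Log2 change (cKO minus WT, x axis) of each tested member of the 14 lists past the camera threshold and of the Kupffer cell and B cell lists (y axis, number tested in brackets). Filled points passed the gene test (red higher, blue lower), open points did not, and bars mark medians, which were 0.96 for stellate cells and fibroblasts and -0.08 for Kupffer cells.

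The remaining lists did not pass as lists, though each held at least 1 gene that changed. Of 42 cell cycle genes 9 were higher and 2 lower, also adjusted over the list alone (median 0.41; camera adjusted p = 0.0627, 0.0118 without WT replicate 3 and 0.0221 without cKO replicate 2), with Cdk1 and Stmn1 higher (log2 change 1.23 and 0.44) and Tk1 lower. Of 34 imprinted genes 11 were higher and 5 lower (12 and 6 adjusted over the list alone; median 0.05; camera adjusted p = 0.064), with Dcn (1.57), Rian, Airn (1.34) and Plagl1 (1.63) higher and H13 lower (-0.33, a call that limma on log2 TPM ended), while without WT replicate 1 or 3 or cKO replicate 3 the list had 0.0493, 0.0484 and 0.0381. Of the 34 imprinted genes 3 are also in other lists, among them Dcn, which is a stellate cell and fibroblast marker too. Plagl1 was too low for the filter of 1 CPM in 4 libraries. Igf2 did not pass (edgeR adjusted p = 0.927) and H19, with at most 18 counts in a library, was not tested. Of 46 drug metabolism genes 12 were higher and 9 lower (13 and 9 adjusted over the list alone; median 0.03; camera adjusted p = 0.311), with Gsta1 at 3.01, Srxn1 at 1.01, Cyp2c39 at 1.05 and Cyp2c37 at -0.94. Of 24 lipoprotein genes 2 were higher and 10 lower (3 and 10 adjusted over the list alone; median -0.20; 0.177), with Apoa4 higher and Apoa2 lower (-0.69). Of 26 bile acid genes 3 were higher and 5 lower (3 and 7 adjusted over the list alone; median -0.11; 0.268), with the transporter genes Abcb1a (2.21) and Abcc4 higher and Hsd3b7 lower (-0.61). Of 27 glucose metabolism genes 11 were higher and 4 lower, also adjusted over the list alone (median 0.21; 0.129, and 0.0478 without cKO replicate 1), with Gbe1 at 0.85 and Pfkfb1 at -0.69.

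Of 34 acute phase and inflammation genes 3 were higher and 9 lower (3 and 11 adjusted over the list alone; median -0.14; camera adjusted p = 0.164, 0.0326 without WT replicate 1 and 0.0269 without WT replicate 2), with Hp at a log2 change of -1.16, Lbp at -0.54 and Ccl5 higher. Of 33 interferon response genes 2 were higher and 9 lower, also adjusted over the list alone (median -0.17; camera adjusted p = 0.138, 0.0261 without WT replicate 2 and 0.0478 without cKO replicate 1), with Psmb8 and Stat2 at -0.62 and -0.59. Of 32 genes of the unfolded protein and integrated stress response 3 were higher and 9 lower (3 and 10 adjusted over the list alone). Their median was -0.29 and the camera adjusted p was 0.702. Nupr1, Atf3 (1.74) and Phgdh (2.81) were higher and Shmt2 lower (-0.36). Phgdh was too low for the filter of 1 CPM in 4 libraries. Of 27 genes of cohesin and genome architecture 7 were higher and 5 lower, also adjusted over the list alone (median 0.02; 0.604), with the cohesin subunits Stag1 and Stag2 at 0.63 each and Mau2 at -0.39, a call that limma on log2 TPM ended. Of 3 clustered protocadherins tested Pcdhgc3 was higher at 1.22 (2 adjusted over the list alone; median 0.29; 0.245). Of 24 pericentral genes 3 were higher and 2 lower (median 0.01; camera adjusted p = 0.959), with Slc1a4 at 1.14. Of 25 periportal genes 5 were higher and 6 lower (median 0.01, mean -0.01, camera direction down, adjusted p = 0.678), with Igfals at -0.83 and Hsd17b13 at 0.69. The counts of both lists were the same adjusted over the list alone.

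Of 20 clock genes 1 was higher and 5 lower, also adjusted over the list alone (median -0.17; camera adjusted p = 0.334), with Nfil3 at a log2 change of -1.04 and Nr1d2 at 0.24. The Nr1d2 call was ended by 7 of 24 alternatives, among them leaving out WT replicate 1, 2 or 3 or cKO replicate 2, 3 or 4 (0.0519 to 0.126). Of 43 ribosomal protein genes Rpl3 and Rpl5 were higher (0.34 and 0.25; 0 adjusted over the list alone; list median 0.01; camera adjusted p = 0.959). Of 24 alternatives 7 ended the call of Rpl5, among them leaving out WT replicate 1, 2 or 3 or cKO replicate 1, 3 or 4 (0.065 to 0.124). Of 15 genes of the mitochondrial genome 0 were higher and 3 lower (0 and 2 adjusted over the list alone, 0 and 6 at an unadjusted p under 0.05, 0 and 5 with DESeq2, 0 and 3 with limma-voom; median -0.22). The camera adjusted p was 0.0872, but 0.0392 with the replicate block, 0.0147 without WT replicate 1 and 0.0162 without cKO replicate 2. The ribosomal RNAs mt-Rnr1 and mt-Rnr2 had log2 changes of -0.64 and -0.42 and mt-Nd4l -0.54. Of 24 alternatives 10 ended the call of mt-Rnr2, among them leaving out WT replicate 2 or 3 or cKO replicate 1, 3 or 4 (0.0574 to 0.103). Genes of the mitochondrial genome took 8.38 ± 0.99% of counts in WT and 7.62 ± 1.07% in cKO (exact two-sided permutation test, p = 0.314). Of 4 sex chromosome genes tested Kdm5d was lower (-0.50, 1 adjusted over the list alone; list median -0.15; camera adjusted p = 0.604). That call was ended by 12 of 24 alternatives, among them leaving out any library but WT replicate 4 (0.0583 to 0.0865).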

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

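The tests of library sex, Mup paralogs and hepatocyte share and the splits for single lists were chosen after the results they bear on were seen, and the other tests before, though the stellate-restricted and portal sets and the bootstrap intervals were drawn up when values of some members were known. Among 312 groups of 4 values examined, 25 had 1 library far from the other 3, where chance gives about 5%. WT replicate 4 stood apart at 1070 CPM of Mup15 (others 29 to 111), 1090 of Mup17 (43 to 164), 94.3 of Mup2 (2.8 to 12.4), 24.9 of Mup8 (2.88 to 4.79), 37.5 of Asns (11.8 to 15.5), 6220 of Ttr (7910 to 8200), 2420 of Cps1 (1680 to 1770) and 9.69 of Marco (5.83 to 6.14). The same library stood apart at 0.187 CPM of Cd3d (0.306 to 0.321), 15.5 of Tbx3os1 (20.6 to 21.4) and 0.0468 of Gldn (0 in the others). WT replicate 3 stood apart at 21 CPM of Hsd3b5 (12.3 to 13.4) and 87 of Angptl8 (34.3 to 40.2), and WT replicate 1 at 280 of Shmt2 (253 to 256).

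Of the cKO libraries, replicate 2 stood apart at 0.0575 CPM of Gm21887 (0 in the others), and replicate 1 stood apart at 0.67 CPM of Nkg7 (1.47 to 1.48), replicate 2 at 469 of Mup7 (87 to 122) and 4770 of Mup3 (3470 to 3680), and replicate 3 at 1.15 of Cldn7 (1.38 to 1.42), 0.61 of Phgdh (1.15 to 1.23), 8.96 of Gsta1 (5.62 to 5.9) and 137 of Srxn1 (93.4 to 99.4). Replicate 4 stood apart at 2.5 of Cyp2g1 (1.92 to 1.98), 4.65 of Cyp2c39 (6.23 to 6.36) and a total of 57.3 M counts (50.3 to 51). Without WT replicate 4 the counts of genes were 2541 higher and 2509 lower.

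The counts of genes were beyond those of every other split of the libraries, but the number of lists was not. Only 1 of the 35 splits of the 8 libraries, the real one, gave as many as 2386 higher genes. Only 1 gave as many as 2352 lower genes, the highest count in a direction among the others being 6. Each of the others mixes the genotypes, which widens the spread within groups, so low counts there were partly built in. The splits bound chance at 1 in 35 and cannot separate genotype from anything else that differed between the groups. For lists, splits with equal numbers of each genotype on either side gave 6 to 17. The others keep part of the genotype contrast, so they are not a pure measure of chance. As many as 14 lists were past the threshold in 16 of the 35 splits, the real one included, and the highest of the others was 21. In a look at single lists made after that count was seen, 3 of the 14 had no other split with a camera p as small; the male-biased list had 5 of 35 splits as small, cholesterol synthesis 6, T and NK cells 7, p53 response 13 and endothelium 22, the real split included.

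Of 23 male-biased genes 15 were lower in cKO and 8 did not pass. Of 19 female-biased genes 7 were higher, 1 was lower and 11 did not pass. With an estimated correlation neither list passed (adjusted p 0.287 and 0.0628). Libraries of different sexes are argued against by Xist, at most 0.263 CPM in any library (scaled to the total alone), with Ddx3y at 11.4 CPM or more (scaled with TMM factors). Reads divided between Mup paralogs are argued against as the whole cause by the 19 male-biased genes that are not Mup genes. Of these 11 were lower and 0 higher, with a median log2 change of -0.895 (bootstrap interval over genes -1.26 to -0.578). That interval treats genes as independent and does not measure the spread between libraries. The estimated correlation in the whole male-biased list was 0.522, so the interval is likely too narrow. Lower growth hormone and STAT5 signalling, which keeps the male pattern, stays open as a biological candidate explanation: Igf1, Socs2 and Cish had a median log2 change of -0.36, but 1 of the 3, Igf1, passed, which met neither bound set beforehand. Under 4 of 24 alternatives Socs2 passed as well, and the bound in favour, a median below -0.3 with 2 of 3 passing, was met: quasi-likelihood without robust (adjusted p 0.0415), the replicate block (0.0429), without cKO replicate 3 (0.0464) and limma-voom (0.0365). A wider set of growth hormone and STAT5 genes was drawn up when the value of Igfals was known. Of 9 tested 2 were lower (Igf1 and Igfals) and 7 did not pass, with a median of -0.21. That set also holds Ghr, Stat5a and Stat5b, which are genes of the pathway and not its targets. Its count and median therefore do not measure the targets alone. Chance stays open for the male-biased list as a set, as 5 of 35 splits, the real one included, gave a camera p as small. Some of the other splits keep part of the genotype contrast, so they are not a pure measure of chance.

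Of 28 stellate cell and fibroblast markers 25 were higher in cKO, though with an estimated correlation the list did not pass (adjusted p 0.0628). A lower share of hepatocytes would raise all other cell types alike. The medians argue against this as the whole cause, as that of these markers lay above that of Kupffer cell markers by log2 1.04 (bootstrap interval over genes 0.889 to 1.35). That interval and those below treat genes as independent and do not measure the spread between libraries. The estimated correlation between genes was 0.802 in the Kupffer cell list and 0.274 in the stellate list, so the interval is likely too narrow. More capsule in the piece of liver taken stays open. Of the 6 mesothelial genes tested 1, Wt1, was higher and 5 did not pass. All but Msln averaged under 1 CPM in both genotypes. The 6 genes had a median of 0.438, which met the bound against this cause set beforehand. Their interval of -0.396 to 0.969, which was not part of that bound, spans it. More portal tract or large vessel stays open as well. The 13 stellate-restricted genes had a median of 0.647 (0.575 to 0.968) and the portal fibroblast and smooth muscle genes one of 0.655. These medians met the bound against this cause set beforehand. The interval of their difference, -0.381 to 0.626, was not part of that bound and leaves either sign possible. Of the 12 portal fibroblast and smooth muscle genes tested 6 were higher, 0 lower and 6 did not pass. Fbln2, Dpt and Entpd2 were higher (log2 change 1.27, 1.12 and 1.07). The smooth muscle genes Acta2, Myh11 and Tagln did not pass (-0.61, -0.65 and 0.34), so the median of this set does not speak for smooth muscle. More stellate cells or more transcript per cell in cKO liver is a further candidate, which bulk RNA does not separate.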

How the results depend on the processing

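Of 3540 values of 151 named genes under up to 24 alternatives, 3370 kept their side of the threshold, 151 calls were lost, 19 were gained and 0 reversed; a change of sign was counted as reversed only if the value or its alternative passed. Of 481 values of lists under 13 alternatives, 437 kept their side, 23 were lost and 21 gained. Thinning and removing the Mup genes were chosen after seeing the data and gave 4597 and 4689 changed genes. Library size alone gave 3624 higher and 1335 lower, and moved the median of all genes to a log2 change of 0.10 (TMM -0.01; limma on log2 TPM 0.12 and 0.14); without the 20 most abundant genes 1442 were lower. An adjusted p under 0.01 left 1180 and 1048, and a null of 1.5-fold 326 and 121, by construction. The log2 TPM values were not scaled with TMM factors. On log2(TPM + 1) 762 were lower and on log2(TPM + 0.1) 756, and Ctcf did not pass (log2 change -0.15, adjusted p 0.119, and -0.18, 0.113; over its alternatives -0.46 to -0.15). Elsewhere the cause was not tested. Leaving out 1 library gave 1752 to 2541 higher and 1629 to 2509 lower genes and 3381 to 5050 in all, and log2 changes of Ctcf of -0.46 to -0.39. Whether the replicate numbers pair the libraries was not settled. Correlations of deviations were 0.0417 to 0.0567 for libraries of the same number and -0.104 to 0.0921 for those of different numbers. Of 4 pairs 2 correlated best with their own number. The replicate block gave 2525 higher and 2416 lower and called the mitochondrial genome list (0.0392). The Xist covariate was not run, as all libraries were low. With an estimated correlation the adjusted p was 0.316 for lipid droplet genes, 0.344 fatty acid synthesis, 0.328 cholesterol, 0.641 fatty acid oxidation, 0.239 hepatocyte identity, 0.596 p53, 0.0628 fetal and tumour genes, female-biased genes and stellate cells, 0.287 male-biased genes, 0.156 lipid-associated macrophages, 0.732 endothelium, 0.229 cholangiocytes and 0.286 T and NK cells. Leaving out 1 library gave ranges of 0.0107 to 0.0847 for fatty acid synthesis, 0.000732 to 0.167 endothelium, 0.00141 to 0.0816 p53, 0.0478 to 0.291 glucose metabolism, 0.0269 to 0.368 acute phase, 0.0261 to 0.368 interferon, 0.0118 to 0.111 cell cycle, 0.0381 to 0.121 imprinted, 0.0147 to 0.24 mitochondrial genome and 0.00232 to 0.903 red blood cell genes. Library size alone lost fatty acid synthesis and endothelium (0.0533 each). With fry, endothelium was lost (0.186), and lipoprotein (0.00629), bile acid (0.0344), cell cycle (0.0269), imprinted (0.00201), protocadherin (0.0126), adipocyte (0.0308) and pancreas and gall bladder genes (0.000554) were gained, though fry does not compare a list with other genes.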

Other observations

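The tests of families and of the 0.5 CPM limit were chosen after results were seen. Those of neighbours and of thinning the 2-fold ratio were set before their own values were seen, but after the counts of higher and lower genes, and of those changed 2-fold, were known. The limits for genes near zero were set earlier. Of 47 Nduf genes tested, which include assembly factors of respiratory complex I and were not tested as a whole, 21 were lower and 2 higher, with a median log2 change of -0.18. Of 29 collagen genes 13 were higher and 3 lower, with a median of 0.51. Collagens are among the stellate cell and fibroblast markers, of which 25 of 28 were higher with a median of 0.96, so the family result is not separate from that list. Of 11 septin genes 7 were higher and 0 lower. Among 236 families of at least 8 tested genes, formed from gene symbols, 5 of 472 tests passed after adjustment, those of Mup (18 of 19 lower), Ndufb (7 of 10 lower), Ndufa (8 of 14 lower), Col and Sept, while Ndufs and Ndufaf did not pass; such tests treat genes as independent, which they are not. Under library size alone the Nduf median was -0.07, with 9 lower and 4 higher, and the Nduf, Mup, collagen and septin medians kept their sign under each of the 5 scalings run.

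Gldn, which encodes gliomedin, had 2 counts over the 4 WT libraries and 845 over the 4 cKO libraries (3.88 ± 0.62 CPM in cKO). Evpl, which encodes envoplakin, stood at 0.358 ± 0.144 and 4.70 ± 0.41 CPM, and Spire2 at 0.033 ± 0.012 and 0.745 ± 0.098 CPM. Gldn, Evpl and Spire2 were picked after their values were seen. The hypothesis that genes near zero in WT and read in cKO outnumber the reverse did not hold at the limits set beforehand, under 0.1 CPM against at least 1 CPM, with 3 genes each way (Gldn, Eif5a2 and Parm1 against Gm21887, AL591207.3 and Fam19a5). A limit of 0.5 CPM, tried afterwards, gave 13 against 3, and is not taken as evidence because it was picked from the same data. With no excess at the planned limits its 3 tests decide nothing: after thinning the ratio was 0.667, 0% of the genes were in the marker lists, and 33.3% had a higher gene within 50 kb.

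Genes changed at least 2-fold were more often higher, at a ratio of 2.09. Deeper cKO libraries are argued against as the cause, as the ratio was 2.03 after thinning to 1 total, with 550 higher and 271 lower genes.

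A further hypothesis was that neighbouring genes change together, since CTCF bounds chromatin domains. For 7944 pairs of neighbours within 50 kb, overlapping genes and genes of 1 family by symbol were left out. The Spearman correlation of log2 changes across genes was 0.14 (0.167 over all 10151 pairs), against at most 0.04 in 1000 shuffles matched on level. Overlapping genes and families by symbol are therefore not the whole cause. Paralogs with other names and reads shared between the remaining neighbours were not left out. Neighbours also varied together within a genotype, where contrasts of 2 against 2 libraries gave 0.0525 to 0.109, and contrasts of 2 cKO against 2 WT libraries gave 0.102 to 0.169. Co-expression of neighbours that any contrast shows therefore cannot be told apart from an effect of genotype, because these ranges overlap and neither bound set beforehand was met.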
